A study of Canis lupus familiaris with 8 samples.

How the data were processed

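RNA sequencing was carried out on 8 libraries of dog cells, from total RNA purified on columns and prepared with the NEBNext Ultra RNA kit, per the labels' protocols. The deposited table holds 1 value per gene and library as TPM, computed by the authors, and each library sums to the common TPM total over the 30424 listed genes. STAR and RSEM and the genome build CanFam3.1 are named per the submitters' processing notes, with no role, version or order. The columns carry the names of gene-level RSEM results, 1 per library, per the file headers, so replicates were not pooled. Whether strand was used in counting, how reads shared between near-identical genes were assigned, and any filter before deposit are not given in the sources used here. The table pairs 15481 gene identifiers with a single symbol and 178 with several, and lists 14765 without a symbol. No per-sample column was left unused.

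TPM keeps no sequencing depth, so the number of reads behind each library is unknown and no counting interval or detection floor was computed. A count model was not used for the same reason. Values exactly at 0 can be failed estimates, since genes that most cells express, such as RPL37, are listed at 0 in some libraries. Such a gene is described as listed at 0, with no fold against that library. Because TPM is a share of the total, a change in a few abundant genes moves all others, and differences between groups were therefore recomputed under other scalings.

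Groups were taken from the labels. The 3 scramble libraries and the 3 libraries labelled KDM2B shRNA were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior, on log2(TPM + 1) of the 11485 genes at 1 TPM or more in at least 3 of the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A difference on this scale understates the fold of genes with low values. Of 32 gene lists (930 genes, 805 with a row of their own), the 30 with at least 5 tested members were compared with all other genes by camera from limma with a preset correlation between genes of 0.01, adjusted over the 30 lists, and again with the correlation estimated per list. The library labelled EC and the untreated JuB2 library are single, so their difference has no test. Genes were compared there when the higher library held at least 10 TPM and were listed when at least 4-fold apart on the log2(TPM + 1) scale. The median of each list, over members at 1 TPM or more in the higher library, was placed among 10000 random lists of the same size. The random lists were drawn from 20 bins of mean expression of all such genes and treat genes as independent. The 200 genes highest in either of these libraries relative to the other were tested with camera in the shRNA comparison. Figures were drawn with matplotlib 3.10.9.

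The genes named were chosen by a rule. For the shRNA comparison it took KDM2B, the 10 largest rises and the 10 largest falls among genes past the threshold with a single symbol, a mean of at least 5 TPM over the 6 libraries and no overlap between the groups, up to 4 members with the smallest p of each list, and the members of the complex that holds KDM2B. For the library labelled EC it took KDM2B, the 10 highest ratios in either direction among genes at least 4-fold apart in the same direction against each scramble library too, and up to 4 members per list with the largest ratio. Some genes that this rule takes are not reported here. A few further genes are named as chosen after their values were seen. The lists, this rule, the comparisons and the alternatives were fixed before the data were examined, apart from those stated to be chosen later. The alternatives were scaling by a trimmed mean of log ratios (30% and 5% trimmed), quantile normalization, no filter on low values, a mean of at least 5 TPM, a pseudocount of 0.1 or 5, no intensity trend, a fit of 8 or of 7 libraries, the replicate number as a block, stricter thresholds, other set tests and leaving out each replicate in turn. Rescaling the nuclear genes without the 13 mitochondrially encoded ones was added after seeing the data.

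The test was tried on simulated data with 200 changed genes among the 11485 genes of the shRNA comparison. It recovered 91.2% and 93.9% of genes changed by -2 and 2 on the log2 scale, 82.4% and 93.9% at -1 and 1, and 36.4% and 33.3% at -0.5 and 0.5. Of its 152 calls, 5.26% were unchanged genes, and 20 simulated data sets with no change gave at most 0 calls. The simulated noise was independent between genes, and values were not rescaled to a common total. The shRNA comparison called 5850 genes, far more than the 200 changed here, so these rates need not hold for it. The reference gene table used for the order of neighbouring genes is of the assembly UU_Cfam_GSD_1.0, which differs from the build of the data, so no coordinates are given.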

Results

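Gene expression was measured by RNA sequencing in 8 libraries of cultured dog cells and given as TPM, the share of transcripts scaled to a common total. JuB2 is a cell line of canine hemangiosarcoma, a malignant tumour with endothelial features. In 3 JuB2 libraries the cells carried a scramble short hairpin RNA (shRNA), a control hairpin, in 3 they were labelled as carrying an shRNA against KDM2B, and 1 was untreated. The remaining library, labelled EC, is described as normal canine endothelial cells. KDM2B is a histone lysine demethylase and a subunit of a variant Polycomb repressive complex, and the series asks how it bears on viability and the DNA damage response in this tumour. Each library listed between 12639 and 13452 genes above 0. Depth is unknown because TPM keeps none. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

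KDM2B (ENSCAFG00000008259), the targeted gene, was higher in the libraries labelled KDM2B shRNA than in scramble. It stood at 20.88, 19.69 and 18.25 TPM in the former and at 14.01, 15.01 and 12.89 TPM in the latter. The means were 19.6 ± 1.32 and 13.97 ± 1.06 TPM (SD, n = 3 each), a difference of 0.46 ± 0.11 on the log2(TPM + 1) scale (SE, limma adjusted p = 0.0101). With trimmed-mean scaling the difference was 0.29 ± 0.10 (limma adjusted p = 0.0492), and the adjusted p ranged from 0.00788 to 0.0492 over the alternatives. The untreated JuB2 library held 17.65 TPM and the library labelled EC 6.83 TPM. The higher KDM2B goes against the label, so each direction given below is that of the libraries labelled KDM2B shRNA relative to scramble and not that of a measured loss of KDM2B transcript. KDM2A, the paralog of KDM2B, rose from 12.8 ± 0.947 to 32.3 ± 4.05 TPM (SD, n = 3 each), by 1.27 ± 0.12 on the log2 scale (SE, limma adjusted p = 0.000166). How reads shared by these paralogs were assigned is not given, which leaves the value of KDM2B uncertain.

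**Figure D1:**
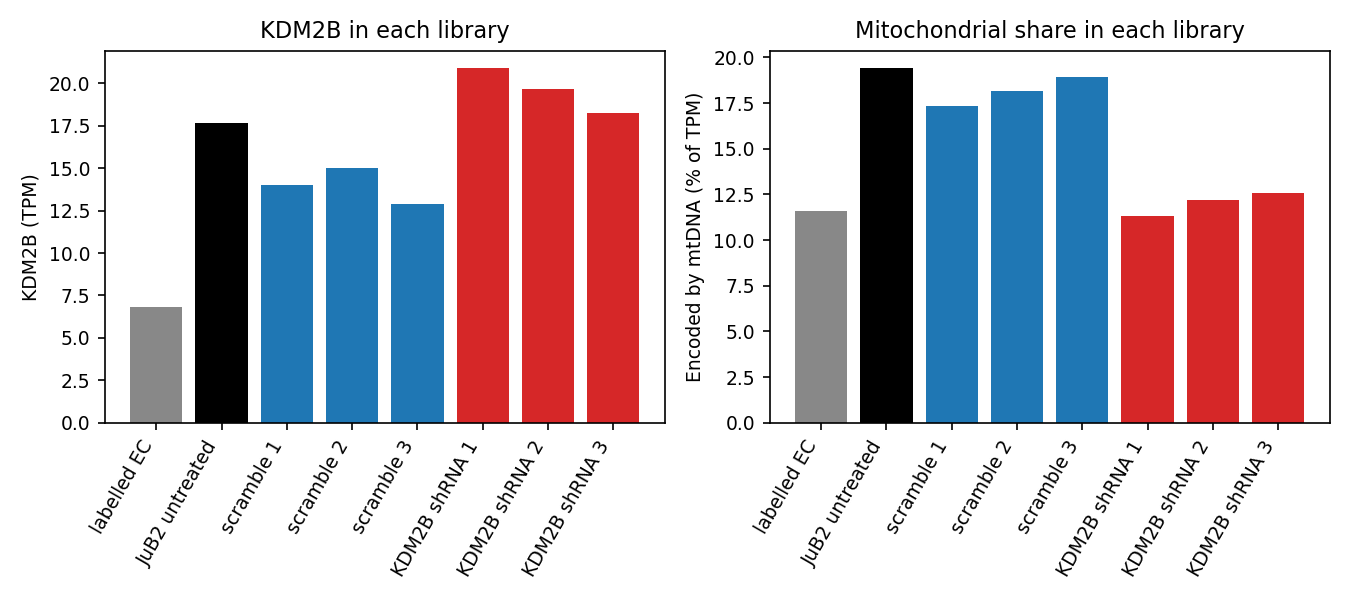
KDM2B in TPM (left) and the share of TPM from the 13 mitochondrially encoded genes in percent (right), 1 bar per library, coloured by group. KDM2B lies between 18.25 and 20.88 TPM in the libraries labelled KDM2B shRNA and between 12.89 and 15.01 TPM in scramble, and the mitochondrial share averages 12.0% and 18.1%.

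Interferon-induced genes made up 5 of the 10 largest rises in the libraries labelled KDM2B shRNA. The largest falls included TAGLN, a smooth muscle gene, and OGN, a proteoglycan gene. ISG15, a ubiquitin-like modifier induced by interferon, rose from 2.73 ± 0.694 to 225 ± 101 TPM (SD, n = 3 each), by 5.85 ± 0.30 on the log2 scale (SE, limma adjusted p = 2.37e-05). OAS1, an activator of antiviral RNA decay, rose by 2.76 ± 0.12 (limma adjusted p = 9.67e-06). USP18, which removes ISG15 from proteins, rose by 2.71 ± 0.31 (limma adjusted p = 0.000338) and LGALS9, a galectin, by 4.09 ± 0.40 (limma adjusted p = 0.00019). The orphan nuclear receptor NR4A1 rose from 5.06 ± 1.61 to 76.8 ± 7.56 TPM, and KLHL41, a sarcomere-associated protein, from 2.93 ± 1.08 to 24.2 ± 2.57 TPM. The other rises among the top 10 had at least 1 scramble library listed at 0. BST2, which tethers virus particles, was at 2.31, 0.7 and 0 TPM in scramble and at 45.96, 97.89 and 46.77 TPM in the libraries labelled KDM2B shRNA. OAS2 was at 0, 0.49 and 0 TPM against 9.83, 19.5 and 9.89 TPM, and CXHXorf56 at 0, 2.47 and 1.94 TPM against 17.38, 13.5 and 15 TPM. The histone gene H2AC13 was listed at 0 in all 3 scramble libraries and at 17.64, 15.31 and 18.14 TPM in the libraries labelled KDM2B shRNA.

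CA2, carbonic anhydrase 2, fell from 346 ± 12.4 to 66.3 ± 2.99 TPM (SD, n = 3 each), by 2.37 ± 0.06 on the log2 scale (SE, limma adjusted p = 9.97e-07). TAGLN, an actin-binding protein of smooth muscle, fell from 291 ± 17.7 to 50.2 ± 11.2 TPM, and OGN, a small proteoglycan, from 23.9 ± 4.86 to 1.63 ± 1.05 TPM. TMEM65, SSBP2 and SYT4 fell from 86.9 ± 6.59 to 13.6 ± 3.604, from 87.2 ± 11.2 to 13.5 ± 3.05 and from 53.7 ± 3.98 to 10.3 ± 0.929 TPM. GGNBP2 and XG fell by 2.59 and 2.49 on the log2 scale. Libraries at 0 occurred for GNG2, at 25.49, 23.02 and 15.46 TPM in scramble against 0, 9.41 and 0 TPM, and for FAM241A, at 30.91, 27.98 and 28.88 TPM against 0, 3.35 and 6.45 TPM. In the untreated JuB2 library CA2 held 148.68, TAGLN 75.04 and OGN 7.14 TPM, so for these 3 genes the scramble libraries also stood above the untreated library. GNG2 was listed at 0 there.

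Of the 11485 genes tested, 5850 passed the adjusted threshold in limma, 3823 higher and 2027 lower in the libraries labelled KDM2B shRNA (65.4% higher). The median gene was 0.16 higher on the log2 scale, and the split depended on this shift: trimmed-mean scaling gave 2628 higher and 2902 lower (47.5% higher) and quantile normalization 2850 higher and 2683 lower (51.5% higher). Rescaling without the mitochondrially encoded genes, chosen after seeing the data, gave 3115 higher and 2484 lower (55.6% higher). With it the median gene was 0.065 higher. A difference of at least 1 on the log2 scale was reached by 1173 of the changed genes, 772 higher and 401 lower. The values of the groups did not overlap for 6805 genes, which is 59.3% where exchangeable libraries give 10%. This count was made on TPM as deposited and not under the other scalings, so the shift of the median gene can add to it. The libraries labelled KDM2B shRNA listed 13420 ± 32.5 genes above 0 and scramble 12719 ± 47.6 (SD, n = 3 each).

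The interferon-stimulated genes rose as a list. Of 24 tested members 19 rose, 1 fell and 4 did not pass, with 19 higher and 1 lower adjusted over the list alone. Their median log2 difference was 1.48 (camera adjusted p = 0.000262, adjusted p = 0.412 with an estimated correlation). DTX3L, a ubiquitin ligase of the interferon response, rose from 1.81 ± 0.647 to 15.3 ± 1.08 TPM. Genes of NF-kB and inflammation rose in 10 of 13 members, with 3 not passing and 11 higher adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.293 with an estimated correlation). Among these CXCL8, a neutrophil attractant, rose from 7.79 ± 1.002 to 27.6 ± 4.91 TPM and TNFAIP3, an inhibitor of NF-kB, from 2.98 ± 0.369 to 10.7 ± 1.79 TPM. ICAM1, an adhesion molecule, rose from 51.2 ± 3.996 to 84.0 ± 3.30 TPM and NFKBIA from 13.1 ± 2.70 to 27.9 ± 2.996 TPM. Immediate early genes, which respond first to growth factors and stress, rose in 15 of 23 members and fell in 2, with 6 not passing and 17 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0352, adjusted p = 0.412 with an estimated correlation). FOSL1 rose from 45.5 ± 7.90 to 131 ± 7.42 TPM, IER2 from 54.7 ± 1.77 to 118 ± 13.1 TPM and NR4A2 from 2.49 ± 0.576 to 13.1 ± 1.67 TPM. In each of these 3 lists the higher members outnumbered the lower ones under every scaling tried.

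MYC targets and genes of ribosome biogenesis rose in 19 of 28 members and fell in 4, with 5 not passing and the same counts adjusted over the list alone (camera adjusted p = 0.0231, adjusted p = 0.521 with an estimated correlation). NOLC1 and NOP2, nucleolar proteins, rose from 28.2 ± 1.34 to 66.2 ± 2.51 and from 30.1 ± 1.06 to 61.2 ± 4.08 TPM. NCL, nucleolin, rose from 336 ± 6.71 to 506 ± 16.1 TPM. MYC itself, on this list, fell from 69.4 ± 2.59 to 33.7 ± 2.14 TPM (SD, n = 3 each), by 1.02 ± 0.08 on the log2 scale (SE, limma adjusted p = 8.08e-05). Ribosomal protein genes went both ways, 19 higher, 21 lower and 20 not passing among 60, with 19 higher and 22 lower adjusted over the list alone and a median of -0.02, below that of all genes (camera adjusted p = 0.044, adjusted p = 0.412 with an estimated correlation). With trimmed-mean scaling 7 were higher and 33 lower. The list did not pass in camera without scramble library 3 (adjusted p = 0.0528), without library 1 labelled KDM2B shRNA (0.0976) or without library 2 labelled KDM2B shRNA (0.0568). RPL6, RPL9, RPL12 and RPL10A fell, the first from 2256 ± 27.3 to 1269 ± 7.51 TPM.

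Matrix genes and targets of TGF-beta fell in 16 of 28 members and rose in 3, with 9 not passing and the same counts adjusted over the list alone (camera adjusted p = 2.02e-05, adjusted p = 0.293 with an estimated correlation). LOXL2, a collagen cross-linking enzyme, fell from 211 ± 1.72 to 71.2 ± 4.35 TPM. The fibrillar collagens COL5A1 and COL5A2 fell from 109 ± 4.24 to 45.3 ± 2.54 and from 229 ± 12.6 to 116 ± 3.49 TPM, and FN1, fibronectin, fell from 396 ± 11.1 to 241 ± 6.03 TPM. Smooth muscle and fibroblast markers fell in 6 of 12 members and rose in 2, with 4 not passing and 2 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0073, adjusted p = 0.341 with an estimated correlation). COL1A2 fell from 644 ± 11.2 to 220.2 ± 10.7 TPM, COL1A1 from 284 ± 2.81 to 140.0 ± 8.96 TPM and ACTA2, smooth muscle actin, from 19.6 ± 1.51 to 6.65 ± 1.55 TPM. Angiogenic ligands and receptors fell in 6 of 21 members and rose in 2, with 13 not passing and 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0073, adjusted p = 0.293 with an estimated correlation). With trimmed-mean scaling 0 of them were higher and 11 lower, and with quantile normalization 1 and 10. VEGFA, the main growth factor of blood vessels, fell from 211 ± 35.9 to 108 ± 10.03 TPM and its co-receptor NRP2 from 101 ± 1.81 to 42.8 ± 1.98 TPM. EFNB2, an arterial ephrin, fell from 42.0 ± 1.72 to 13.2 ± 1.08 TPM and PDGFRA from 32.1 ± 1.23 to 19.9 ± 2.60 TPM.

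Genes of the unfolded protein and amino acid stress responses fell in 18 of 27 members and rose in 6, with 3 not passing and 6 higher and 19 lower adjusted over the list alone (camera adjusted p = 4.16e-05, adjusted p = 0.293 with an estimated correlation). ASNS, asparagine synthetase, fell from 198 ± 8.73 to 63.9 ± 4.17 TPM, TRIB3, a stress-induced pseudokinase, from 313 ± 15.7 to 105 ± 9.93 TPM and MTHFD2, a mitochondrial folate enzyme, from 224 ± 5.68 to 108 ± 5.41 TPM. MANF, a chaperone of the endoplasmic reticulum, rose from 393 ± 11.7 to 698 ± 8.54 TPM. The 13 mitochondrially encoded genes fell in all members, with the same count adjusted over the list alone (camera adjusted p = 5.86e-11, adjusted p = 0.293 with an estimated correlation), but with quantile normalization 2 were higher and 7 lower. Among them CYTB fell from 3849 ± 16.6 to 1728 ± 42.0 TPM and COX1 from 20483 ± 492 to 10375 ± 253 TPM. ND2 fell from 8333 ± 38.3 to 4506 ± 184 TPM and COX2 from 17853 ± 284 to 9961 ± 504 TPM. Their share of the TPM was 18.1 ± 0.786% in scramble and 12.0 ± 0.646% in the libraries labelled KDM2B shRNA (SD, n = 3 each), 19.4% in untreated JuB2 and 11.6% in the library labelled EC. None of these 10 lists passed the threshold with an estimated correlation, and camera compares a list with other genes and is not moved by the median shift.

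**Figure D2:**
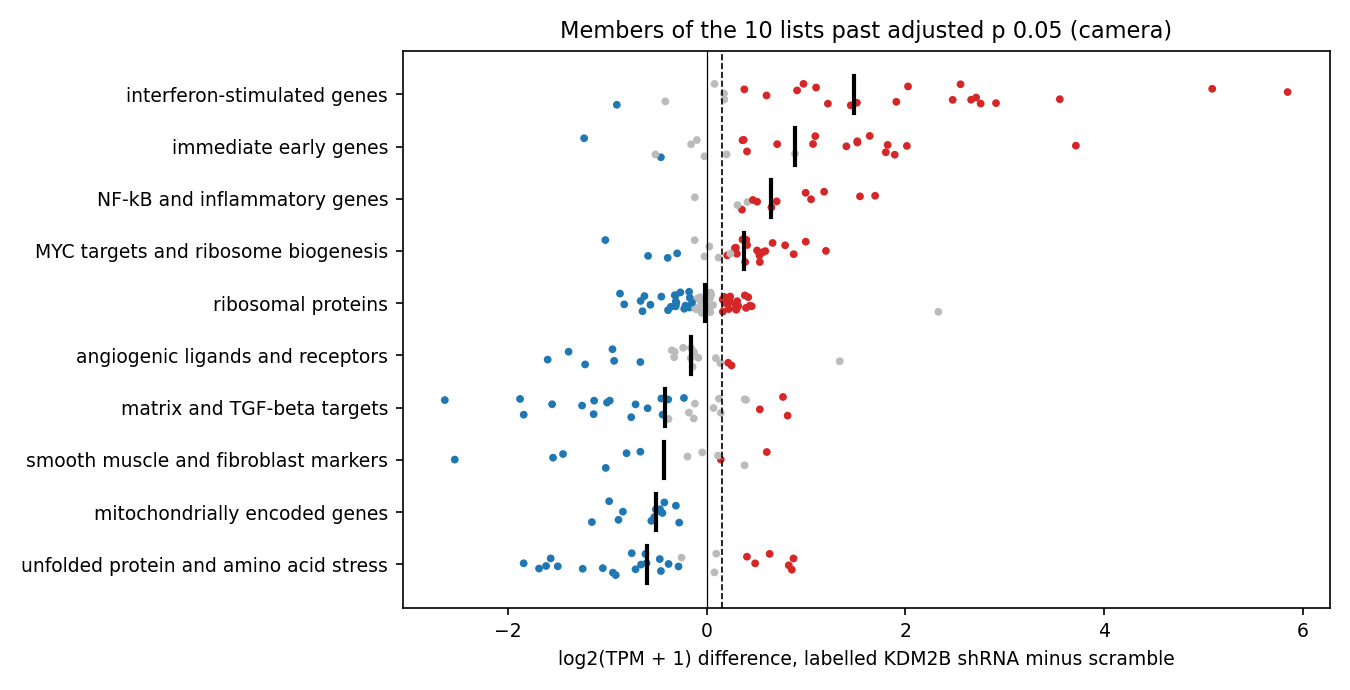
Difference in log2(TPM + 1) between the libraries labelled KDM2B shRNA and scramble (horizontal axis) of the tested members of the 10 lists past the camera threshold (vertical axis). Each point is a gene, red for higher, blue for lower and grey for not passing in limma, black bars are list medians, the dashed line is the median of all genes at 0.16, and the interferon-stimulated genes lie farthest right with a median of 1.48, while with quantile normalization 2 mitochondrially encoded genes were higher and 7 lower.

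The DNA repair and damage lists went both ways and none passed in camera. DNA damage signalling had 8 members higher, 4 lower and 11 not passing of 23 (the same adjusted over the list alone, camera adjusted p = 0.763), and with trimmed-mean scaling 6 were higher and 8 lower. CDC25A, a phosphatase that starts the cell cycle, rose from 11.4 ± 1.06 to 29.6 ± 2.30 TPM and CLSPN, a checkpoint adaptor, from 13.3 ± 0.627 to 29.6 ± 1.39 TPM. H2AX, the histone marked at breaks, rose from 92.0 ± 12.7 to 181 ± 9.68 TPM and RAD17 from 40.2 ± 2.42 to 64.8 ± 1.40 TPM. Homologous recombination and Fanconi anaemia genes had 10 higher, 6 lower and 18 not passing of 34 (the same adjusted over the list alone, camera adjusted p = 0.673), and 8 higher and 9 lower with trimmed-mean scaling. Of these FANCD2 and BARD1 fell from 58.6 ± 1.77 to 37.9 ± 2.97 and from 57.7 ± 3.05 to 38.6 ± 2.19 TPM. EXO1 and UBE2T rose from 13.3 ± 0.748 to 22.1 ± 1.60 and from 116 ± 8.58 to 163 ± 12.7 TPM. End joining had 1 higher and 2 lower of 14 with 11 not passing (the same adjusted over the list alone, camera adjusted p = 0.232), and 1 higher and 4 lower with trimmed-mean scaling. Its member MAD2L2 fell from 99.9 ± 6.78 to 58.2 ± 9.09 TPM and XRCC6, a subunit of Ku, rose from 55.9 ± 2.45 to 77.6 ± 5.85 TPM.

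Mismatch and base excision repair had 10 higher, 4 lower and 11 not passing of 25, with 11 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.914), and 6 higher and 6 lower with trimmed-mean scaling. MSH3, a mismatch recognition gene, fell from 16.4 ± 1.16 to 7.80 ± 0.286 TPM. POLB fell from 32.2 ± 6.399 to 13.5 ± 1.67 TPM, and the glycosylase OGG1 rose from 21.6 ± 3.75 to 57.7 ± 4.16 TPM. Nucleotide excision repair had 6 higher, 5 lower and 11 not passing of 22, with 7 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.605), and 3 higher and 9 lower with trimmed-mean scaling. ERCC4 and DDB2 rose from 13.4 ± 1.55 to 23.0 ± 1.52 and from 8.31 ± 1.43 to 16.8 ± 2.02 TPM. DNA replication had 17 higher, 5 lower and 13 not passing of 35 (the same adjusted over the list alone, camera adjusted p = 0.638), against 9 higher and 13 lower with trimmed-mean scaling. UHRF1, RRM2 and MCM2 rose from 57.5 ± 2.31 to 128 ± 5.98, from 338 ± 15.3 to 591 ± 32.5 and from 148 ± 5.86 to 240.0 ± 9.05 TPM. MCM6 fell from 227 ± 5.26 to 134 ± 6.22 TPM. Mitosis genes were higher in 14, lower in 4 and not passing in 14 of 32 (the same adjusted over the list alone, camera adjusted p = 0.443), and 10 were higher and 9 lower with trimmed-mean scaling. AURKA, CCNB1, CDC20 and MKI67 rose.

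Genes of the p53 response and cell death went both ways. The p53 targets had 5 higher, 5 lower and 12 not passing of 22 (the same adjusted over the list alone, camera adjusted p = 0.673), and 3 higher and 5 lower with trimmed-mean scaling. CDKN1A, a cell cycle inhibitor, rose from 52.7 ± 1.16 to 88.5 ± 7.21 TPM and POLH, a lesion-bypass polymerase, from 12.8 ± 2.47 to 34.8 ± 1.37 TPM. The untreated JuB2 library held 90.49 TPM of CDKN1A, above scramble, and 13.38 TPM of POLH. CCNG1 and SESN2 fell. Apoptosis regulators had 4 higher, 3 lower and 14 not passing of 21, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.735), and 4 higher and 5 lower with trimmed-mean scaling. APAF1, the apoptosome scaffold, fell from 21.8 ± 0.93 to 13.1 ± 0.378 TPM and BCL2L11, a pro-apoptotic protein, rose from 15.5 ± 1.57 to 22.9 ± 1.22 TPM. Cyclin-dependent kinase inhibitors and senescence genes rose in 7 and fell in 2 of 11 with 2 not passing (the same adjusted over the list alone, camera adjusted p = 0.206), CDKN2C from 42.3 ± 3.49 to 103 ± 16.4 TPM.

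Among the 11 genes of the complex that holds KDM2B, 5 rose, 1 fell and 5 did not pass, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.539). RING1, CBX8, BCORL1 and BCOR rose beside KDM2B, RING1 from 72.5 ± 1.94 to 96.0 ± 5.82 TPM and CBX8 from 3.90 ± 0.332 to 8.73 ± 1.93 TPM. The untreated JuB2 library held 94.95 TPM of RING1, so for this gene scramble stood below it. It held 3.38 TPM of CBX8, 0.6 of BCORL1 and 6.55 of BCOR. SKP1 fell from 390 ± 34.8 to 314 ± 13.3 TPM. The values of RYBP, USP7, YAF2, RNF2 and PCGF1 did not pass, at 21.2 ± 5.86 and 32.1 ± 5.90, 33.5 ± 3.19 and 38.3 ± 1.36, 32.2 ± 0.744 and 24.7 ± 10.8, 30.3 ± 2.54 and 26.5 ± 4.70, and 16.5 ± 4.56 and 21.0 ± 5.42 TPM. RYBP passed in limma without scramble library 1 (0.73 on the log2 scale) or without library 2 labelled KDM2B shRNA (0.75), and with the replicate number as a block, YAF2 passed without that library 2 (-0.77), and BCORL1 did not pass with quantile normalization. Other Polycomb genes were 7 higher, 2 lower and 14 not passing of 23 (the same adjusted over the list alone, camera adjusted p = 0.673). PHC2 rose from 77.5 ± 1.03 to 140 ± 11.6 TPM and PHF1 from 14.7 ± 1.15 to 32.1 ± 3.43 TPM. The histone lysine demethylases were 9 higher, 2 lower and 9 not passing of 20 (the same adjusted over the list alone, camera adjusted p = 0.673), and 6 higher and 5 lower with trimmed-mean scaling. KDM6A rose from 9.62 ± 0.737 to 19.2 ± 0.892 TPM. HOX genes, patterning genes under Polycomb control, rose in 10 of 20 and fell in 0, with 10 not passing and the same adjusted over the list alone (camera adjusted p = 0.0624), and 5 were higher and 0 lower with trimmed-mean scaling. The list passed in camera only without scramble library 1 or without library 1 labelled KDM2B shRNA (adjusted p = 0.0421 in either case). HOXD10 rose from 4.76 ± 1.44 to 13.8 ± 1.94 TPM.

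The remaining lists did not pass in camera. Heat shock and oxidative stress genes rose in 11 and fell in 5 of 21 with 5 not passing (the same adjusted over the list alone, camera adjusted p = 0.452). HSPA8, the constitutive cytosolic chaperone, rose from 731 ± 28.7 to 3515 ± 85.2 TPM (SD, n = 3 each), by 2.26 ± 0.04 on the log2 scale (SE, limma adjusted p = 1.06e-07), with 1187.9 TPM in untreated JuB2. HSP90AA1, DNAJB1 and DNAJA1 rose by 0.97, 1.56 and 1.03 on the log2 scale. Genes of hypoxia and glycolysis had 15 higher, 4 lower and 11 not passing of 30 (the same adjusted over the list alone, camera adjusted p = 0.426), and 9 higher and 9 lower with trimmed-mean scaling. Nuclear genes of mitochondrial respiration had 17 higher, 6 lower and 17 not passing of 40 (the same adjusted over the list alone, camera adjusted p = 0.452), and 10 higher and 10 lower with trimmed-mean scaling. Cholesterol synthesis had 6 higher, 6 lower and 9 not passing of 21, with 6 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.76), and 4 higher and 8 lower with trimmed-mean scaling. Antigen presentation rose in 5 and fell in 0 of 11 with 6 not passing (the same adjusted over the list alone, camera adjusted p = 0.175), among them CALR from 410 ± 11.9 to 561 ± 13.5 TPM and B2M from 702 ± 23.3 to 1004 ± 90.7 TPM. Endothelial markers were higher in 7 and lower in 0 of 11 with 4 not passing (the same adjusted over the list alone, camera adjusted p = 0.141), and 7 higher and 1 lower with trimmed-mean scaling. Among them ETV2, a transcription factor of endothelial fate, rose from 109 ± 3.82 to 194 ± 11.4 TPM. It was also at 105.88 TPM in untreated JuB2 and at 65.21 TPM in the library labelled EC. Whether all reads given to ETV2 come from that gene was not tested. The 3 leukocyte markers tested had 2 higher and 0 lower, against 0 higher and 1 lower with trimmed-mean scaling, and the 4 epithelial markers 2 higher and 1 lower, too few for camera. The lists of homologous recombination, p53 targets, apoptosis and cholesterol synthesis had a median above 0 while the direction of camera, which did not pass, was down. Nucleotide excision repair had a median of -0.01 and a mean of 0.08, with the same direction in camera, which did not pass.

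The library labelled EC held high levels of smooth muscle, fibroblast and matrix genes, and of 33 endothelial markers 7 reached 10 TPM in it and 7 in untreated JuB2. It held 3527 TPM of DCN and 6443 TPM of SFRP2, both listed at 0 in untreated JuB2. It held 5319 TPM of ACTA2 against 11.06, 6546 TPM of TAGLN against 75.04 and 2460 TPM of LUM, a small proteoglycan, against 1.13. Of the endothelial markers, PECAM1 and VWF, an endothelial adhesion molecule and a clotting factor carrier, were listed at 0 in the library labelled EC. CDH5, the endothelial cadherin, was at 0.64 and KDR, the main VEGF receptor, at 1.24 TPM. In untreated JuB2 PECAM1, VWF and CDH5 were listed at 0 as well and KDR was at 4.77 TPM. The library labelled EC was higher in PDPN, a lymphatic endothelial and fibroblast glycoprotein, with 267 TPM where JuB2 was listed at 0, and in ERG, an endothelial transcription factor, at 21.93 against 1.28 TPM, while ENG was at 37.04 and 22.03 TPM. KDM2B was at 6.83 TPM in it and 17.65 in untreated JuB2, a log2(TPM + 1) difference of -1.25. With 1 library on either side these values have no replicate check.

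**Figure D3:**
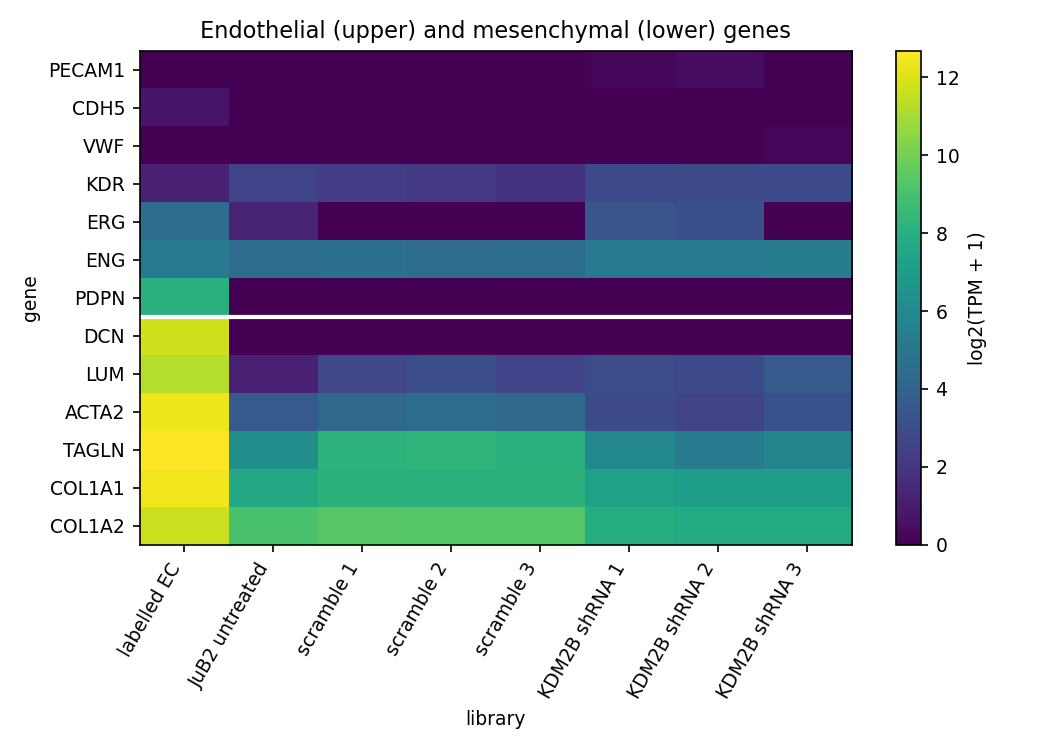
Expression as log2(TPM + 1), given by colour, of endothelial genes (upper rows) and smooth muscle, fibroblast and matrix genes (lower rows) in the 8 libraries (columns). In the library labelled EC the lower rows are at their highest values, ACTA2 at 5319 TPM, while PECAM1 and VWF are listed at 0.

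Of 8805 genes at 10 TPM or more in the higher of the pair, 618 were at least 4-fold higher in the library labelled EC and 651 in untreated JuB2, on the log2(TPM + 1) scale. These include 296 genes listed at 0 in either library, 209 in untreated JuB2 and 87 in the library labelled EC, where a 0 can be a failed estimate and no fold is given. For 1000 of these 1269 genes each scramble library stood at least 4-fold apart from the library labelled EC in the same direction. Further genes of the highest ratios in the library labelled EC were TFPI2 at 1649 TPM, THBS2 at 1433, IGFBP2 at 2518, COL6A1 at 1376, TPM2 at 3533, ASPN at 833 and VCAN at 1150 TPM, each under 3 TPM in untreated JuB2. Untreated JuB2 held 234 TPM of TPD52, 149 of CA2, 103 of TFF1, a mucosal peptide, 82.7 of GUCY1B1, 76.7 of DKK2 and 72.6 of CHCHD7, all 6 listed at 0 in the library labelled EC. It also held 223 TPM of the keratin gene KRT75, 107 of LIPC and 104 of TSPAN13. The median gene was 0.34 lower in the library labelled EC on the log2 scale. Under trimmed-mean scaling 778 genes were higher and 412 lower in it.

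Gene lists also set these libraries apart. The median member of the smooth muscle and fibroblast list was 4.58 higher in the library labelled EC on the log2 scale, and that of the matrix list 2.76 higher, both at the 100th percentile of random lists. Immediate early genes, with FOS at 431.5 and 5.18 TPM, had a median of 1.05 at the 100th percentile. Endothelial markers had a median of 0.78 at the 99.3th percentile, hypoxia and glycolysis one of 0.59 at the 99.97th and angiogenic genes one of 0.32 at the 99.2th. The endothelial median covers only 18 of the 33 markers. Of these 2 were at least 4-fold higher in the library labelled EC and 1 in untreated JuB2. In the library labelled EC 11 of the 33 were listed at 0. Lower in the library labelled EC were mitosis genes, with a median of -1.22 at the 0th percentile, DNA replication, with -0.95 at the 0.04th, and homologous recombination and Fanconi anaemia genes, with -1.001 at the 0.65th. With trimmed-mean scaling the medians of hypoxia and glycolysis and of angiogenic genes were 0.97 and 0.70, that of endothelial markers 1.02, and those of mitosis, DNA replication and homologous recombination genes -0.88, -0.58 and -0.68. With a pseudocount of 5 the median of endothelial markers was 0.25, and against the scramble mean that of angiogenic genes was 0.17. PCNA, a replication clamp, was at 130.27 TPM in it and 587 in untreated JuB2, CCNE2, an S-phase cyclin, at 3.2 and 58.9 TPM, and BARD1 at 6.51 and 49.9 TPM.

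Few genes set scramble JuB2 apart from untreated JuB2. Of 8246 genes, 39 were at least 4-fold apart between the scramble mean and the untreated library, 28 higher and 11 lower in scramble, and each scramble library alone stood 41 to 54 genes apart. For 31 of the 39 genes the scramble mean or the untreated library was listed at 0, which can be a failed estimate. Each library labelled KDM2B shRNA was 151 to 162 genes apart from the untreated one. Across 11774 genes, which are not independent replicates, the untreated library correlated with the scramble libraries at 0.968 to 0.97, with those labelled KDM2B shRNA at 0.928 to 0.93 and with the library labelled EC at 0.745.

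The 200 genes with the highest ratio of untreated JuB2 over the library labelled EC went both ways in the libraries labelled KDM2B shRNA. Of these genes 66 fell and 42 rose, with a median log2 difference of -0.09 (camera p = 0.000236, adjusted p = 0.000472, adjusted p = 0.0786 with an estimated correlation). The camera p of this set was also under 0.05 in each of the 9 other splits of the 6 libraries into groups of 3. The 200 genes with the highest opposite ratio had 58 higher and 39 lower and a median of 0.14, close to that of all genes (camera from limma, p = 0.257, adjusted p = 0.257, adjusted p = 0.366 with an estimated correlation). Across 8534 genes the EC difference and the shRNA difference correlated weakly, with Pearson's r of 0.097 and Spearman's rho of 0.0931, and genes are not independent replicates.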

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

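Leaving out mitochondrially encoded genes, and leaving out single scramble libraries in the comparison with untreated JuB2, were chosen after seeing the data. All other alternatives were planned. The count of 5850 genes fell to 3857 at an adjusted p of 0.01 and to 1173 with an added log2 difference of at least 1, by construction, and stayed within 5060 to 5165 with any 1 library left out. KDM2B stayed higher in the libraries labelled KDM2B shRNA under each alternative, from 0.29 with trimmed-mean scaling to 0.51 without a library, with limma adjusted p from 0.00788 to 0.0492. The 10 lists of camera became 0 with an estimated correlation and 24 with fry, which does not compare a list with other genes, and 9 to 11 without a library, where ribosomal proteins lost and HOX genes gained a call. With a pseudocount of 5 the 1269 genes apart between the library labelled EC and untreated JuB2 became 789, and with 2-fold as the limit 3513, by construction. CD79A, whose difference of 0.17 was close to the shift of the median gene, was at -0.0072 on the log2 scale with trimmed-mean scaling. In the library labelled EC the list medians of nucleotide excision repair, p53 targets, other Polycomb genes and mitochondrial respiration turned from lower to higher with that scaling, at 0.186, 0.094, 0.146 and 0.0097, by construction, since it applies 1 factor to each library and raised the median of every list. The median of the complex that holds KDM2B also turned with this scaling, from -0.29 to 0.083. The median of the histone lysine demethylases turned from -0.065 to 0.285. Before scaling, both medians lay within the spread between scramble libraries. Counting these but not the lists named first, 70 values of EC list medians under alternatives moved by more than this spread, and 50 did not. Of the values of single genes named in the EC comparison 389 moved and 171 did not. Single genes named in the shRNA comparison lost their call in 21 and gained one in 11 of their values under alternatives. A further 2439 values kept their side of the threshold, with the same direction wherever the gene passed. Genes that passed in neither fit may have changed direction among these. The replicate number as a block gave 5448 genes, and changed no list. Deviations of same-numbered samples correlated at 0.0339, 0.0115 and -0.0464, and not every sample correlated best with its own number. No strong shared deviation was thus seen, but with so few libraries per group this cannot tell whether the numbers mark a pairing. Depth limits nothing that can be stated, since TPM keeps none.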

Other observations

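Genes not described above also differed between the libraries labelled KDM2B shRNA and scramble, where the label goes against the KDM2B transcript. The tests of the patterns below were chosen after the results were seen, except the regrouping of the libraries. A total of 22 genes were listed at 0 in each scramble library and at 1 TPM or more in each library labelled KDM2B shRNA, against 4 genes the other way. The libraries labelled KDM2B shRNA listed more genes above 0 in general, 13420 ± 32.5 against 12719 ± 47.6 in scramble (SD, n = 3 each). The excess of 22 over 4 thus need not be particular to these genes. Among the 22 were the interferon-induced IFI6 at 5.27, 10.62 and 4.86 TPM and RTP4 at 2.76, 6.75 and 2.14 TPM, the patterning gene HOXA6 at 11.77, 1.88 and 5.39 TPM and FAM13C at 3.94, 3.57 and 3.4 TPM, chosen after their values were seen. HOXA6 held 4.09 TPM in untreated JuB2, and 15 of the 22 genes were listed at 0 there.

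Splicing regulators, a family of 33 SRSF, HNRNP and CLK genes chosen after seeing the data, had 20 members higher and 2 lower, with a median log2 difference of 0.29. With trimmed-mean scaling 15 were higher and 3 lower. CLK4, a kinase of splicing factors, rose from 3.34 ± 0.3 to 12.2 ± 1.04 TPM and SRSF7 from 196 ± 11.5 to 309 ± 13.8 TPM. Because the family was chosen on these libraries, its camera p of 0.000753, and p = 0.133 with an estimated correlation, restate that choice, and whether the family rose relative to other genes stays open. CD79A, a B cell receptor gene, was at 1617 to 3056 TPM in each of the 8 libraries while 17 of the 21 leukocyte markers stayed under 1 TPM in every library. In the reference gene table RPS19, a ribosomal protein gene, is a neighbour of CD79A, and no row of the deposited table carries its symbol.

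KDM2B was higher in the libraries labelled KDM2B shRNA. A shift of the TPM scale is argued against, since the lowest difference over 3 other scalings was 0.29, at 2.84 times its standard error. An exchange of the shRNA labels cannot be told apart from correct labels: the untreated library correlated with the libraries labelled KDM2B shRNA at no more than 0.93 and with scramble at no less than 0.968, yet its KDM2B lay 1.96 TPM from the former mean and 3.68 TPM from the latter, and it is a single library. Reads shared with KDM2A also stay open, since KDM2B gained 0.289 ± 0.0615 TPM (SE) per TPM of KDM2A. The lowest ratio of KDM2B to KDM2A in a library was 0.327, that of the library labelled EC, which holds other cells. Library 1 labelled KDM2B shRNA was highest in both genes, at 20.88 and 36.95 TPM. The 2 genes did not rank all libraries alike, as scramble library 2 had the most KDM2B of scramble, 15.01 TPM, and the least KDM2A, 11.7 TPM. A hairpin that lowers protein more than transcript was not tested.

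Interferon-stimulated genes were higher in the libraries labelled KDM2B shRNA. A single library is argued against, since leaving out any 1 of the 6 gave a camera p of 0.000115 at most with the preset correlation, although with an estimated correlation the list did not pass with all 6 (p = 0.165). RNA of leukocytes stays open: 0 of 21 leukocyte markers reached 1 TPM on average in these libraries while staying under 1 TPM in scramble, but 17 of the 21 were under 1 TPM in every library, so it is not shown that their gene models take reads. Expression of a hairpin as such stays open: the median log2 difference of the list was 0.0562 between scramble and untreated JuB2 against 1.48 between the shRNA groups, but with 1 untreated library, and the sequence and dose of the hairpins may differ. An effect of KDM2B was not separated from an effect of that hairpin.

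The library labelled EC held PECAM1, VWF and CDH5 under 1 TPM and high levels of mesenchymal markers. An exchange with the untreated JuB2 library is argued against, since its correlation with a scramble library was at most 0.745 where that of the untreated library was at least 0.968. Gene models that take no reads stay open for part of the markers: 10 of 33 endothelial markers reached 10 TPM in some library, and 14, among them PECAM1 and VWF, were under 1 TPM in every library. Smooth muscle or fibroblast cells in the culture are a candidate that their markers cannot test, since the high levels of these markers are the pattern itself. Of the 20 markers 16 were at 10 TPM or more in the library labelled EC, 7 of them at 1000 TPM or more. In untreated JuB2 10 of the 20 reached 10 TPM too, and 2 stand on another list. A change of endothelial cells towards a mesenchymal state in culture was not tested.

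The 6 shRNA libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 5850 changed genes and the highest other split 1, and it gave 10 lists where the highest other gave 5. Each other split mixes the shRNA groups, so a difference between them, from whatever source, widens the spread within its sides. The low gene counts of these splits were therefore to be foreseen and say nothing of the cause. For the genes higher in untreated JuB2 the camera p was 0.000236 and those of the other 9 splits lay between 0.00507 and 0.0469, each under 0.05 with at most 1 changed gene, so this set passes with the preset correlation under every regrouping. For those higher in the library labelled EC the p was 0.257 and the lowest of the other splits 0.283. In each case 1 split, the real one, reached the value.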
